A study of Mus musculus with 4 samples.

How the data were processed

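The study measured single-cell transcriptomes of 4 samples, 1 library each, from lungs of Gramd2creERT2;mTmG mice: sorted GFP-positive cells (day 0) and organoid cultures of such cells at days 8, 13 and 20. Per the labels' protocols, libraries were made with the Chromium Single Cell 3' kit v3.1 from single-cell suspensions, while the labels give the molecule as nuclear RNA. The deposited counts are raw UMI counts per gene and barcode, made with Cell Ranger 7.0.1 against mm10, per the submitters' processing notes, with EGFP and tdTomato as added features. The annotation behind the counts, any correction for free RNA and any removal of doublets are not given in the sources used here. Each library listed the same 22547 features, and the smallest total was 500 UMIs per barcode in all 4. The feature name Gramd2 stands for the gene also called Gramd2a, and Ccn2 and Ccn1 were read for the list entries Ctgf and Cyr61.

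Cells were kept with at least 500 detected genes and at most 15% mitochondrial UMIs, which left 7350, 7893, 9311 and 9178 cells at days 0, 8, 13 and 20. The share of barcodes above 15% mitochondrial UMIs was 3.80, 29.3, 16.7 and 9.45%, and 1415, 2564, 1335 and 617 barcodes had too few genes. Doublet scores were computed per library with Scrublet in Scanpy 1.11.5. Its automatic threshold called 315 cells (3.99%) at day 8 and 0 in the other 3 libraries, where it did not work, so the cells with the highest scores were removed at a rate of 0.8% per 1000 barcodes (523, 719, 853 and 761 cells). Before doublet removal the kept cells had median depths of 2558, 17075, 9527 and 12791 UMIs. Cells of all 4 libraries were clustered together on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, with no batch integration because library and day coincide.

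No cell annotation by the authors was used, so classes were rebuilt and may differ from theirs. Each cluster took the name, written X-like, of the marker list with the highest mean deviation, out of 15 lists: AT1, AT2, transitional, airway secretory, basal, ciliated, cycling (a state, never a name), mesenchymal, smooth muscle and pericyte, endothelial, myeloid, lymphoid, mesothelial, neuroendocrine and erythroid. A cluster stayed unnamed with under 3 detected markers, with as many or more markers of another class among its 10 leading genes, or with a median depth under 1/3 of its library's and no marker of its own among those genes. The choice of cells against which leading genes were ranked was made after seeing the data. AT1, AT2, airway secretory, basal and ciliated clusters formed the epithelial class. Epithelial cells were also clustered alone at resolution 1.0, a step added after seeing the data.

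UMI counts were summed over the cells of a class per library and scaled to that sum as CPM. With 1 library per day no test was made. Ratios between days carry an exact conditional Poisson interval, CPM an exact Poisson interval and shares of cells a Clopper-Pearson interval, all at 95%. A gene counted as higher or lower when the ratio was at least 2-fold, the larger library had at least 20 CPM and the interval excluded 1. A side with fewer than 3 UMIs was set to 3, and a ratio is written as a lower bound when that side had 0. The contrasts were day 8 against day 0, day 13 against day 8, day 20 against day 13 and day 20 against day 0, in epithelial cells and in classes with at least 50 cells in both libraries.

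Genes are named by a rule set with the lists before the data were examined. It takes the 12 largest ratios in each direction at day 8 against day 0 and the 8 largest at each later step, among genes with at least 50 CPM that met the 2-fold rule. It leaves out mitochondrial, ribosomal, haemoglobin, immunoglobulin, Xist and Y-linked genes and predicted models. It adds up to 4 members of each list and a fixed set of key genes. Besides the marker lists there were 22 pathway lists: surfactant lipid and lamellar body, MHC class II, lung transcription factors, epithelial junctions, epithelial-mesenchymal transition, TGF-beta targets, YAP/TAZ targets, p53 targets, S phase, immediate early and heat shock, interferon response, NF-kB and chemokines, glycolysis and hypoxia, cholesterol synthesis, fatty acid synthesis, Wnt targets, Notch pathway, FGF/EGF feedback, NRF2 targets, caveolae and vascular crosstalk of AT1 cells, basement membrane and gastrointestinal epithelium. A list is described by its members with at least 5 CPM in any library, how many were higher or lower, the median log2 ratio, and the percentile of that median among 10000 random lists of the same size matched on expression, which describes these libraries only. Of the genes so chosen 3 are not reported here, while they stay in the counts and medians. Within classes and at later steps, genes outside the rule are named from the lists with their values.

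Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs, with shallower cells left out. Cells with at least 2 reporter UMIs were put in ranges: EGFP-dominant with at least 80% EGFP, tdTomato-dominant with at most 20%, and between. These are ranges, not cell types, and they were set after seeing the data. Coordinates come from the GENCODE vM21 annotation of GRCm38, the assembly also called mm10, matched by Ensembl identifier.

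The ratio step was tested on Poisson counts simulated from 1 epithelial mean profile, pooled over all days, with the library sizes of each contrast. In each run 200 genes were changed among 22547. The simulation held no difference in cell mix between days, so it checks the calling rule and not the real contrasts. For day 8 against day 0 it called 97.0% of 2.5-fold, 98.5% of 4-fold and 98.5% of 8-fold genes, for day 13 against day 8 98.5%, 100% and 98.5%, for day 20 against day 13 100%, 100% and 100%, and for day 20 against day 0 98.5%, 98.5% and 98.5%. None of the 5569, 5526, 5545 and 5588 unchanged genes was called in the 4 contrasts. The intervals of unchanged genes held a ratio of 1 in 80.5, 54.5, 81.4 and 89.0%, less than 95%, because changed genes moved the total to which CPM is scaled.

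Alternatives covered median-of-ratios scaling, minimum CPM of 5 and 100, the mean over cells, all filtered cells, no cell filter, a filter of 1000 genes and 10% mitochondrial UMIs, doublets kept, Scrublet's automatic threshold, Leiden resolutions 0.5 and 2.0, each library clustered on its own, list members with at least 50 CPM, and thinning to 1000 UMIs or not at all. Added after seeing the data were leaving out the epithelial sub-clusters led by myeloid or mesenchymal genes, leaving out the Krt13-high cluster, and other limits for the reporter ranges. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used with a fixed seed.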

Results

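Lung cells of Gramd2creERT2;mTmG mice were profiled by droplet single-cell RNA-seq. In this strain a Cre recombinase under the control of Gramd2, a gene of alveolar type I (AT1) cells, turns a membrane tdTomato reporter into membrane EGFP. GFP-positive cells sorted from the lung formed the day 0 sample. The same kind of sorted cells, embedded in Matrigel with MLg cells, a mouse lung fibroblast line, and an inhibitor of TGF-beta receptors, gave the organoid samples of days 8, 13 and 20, which were enriched for EpCAM-positive cells on magnetic beads before loading. Each of the 4 days had 1 library, so no difference between days has a replicate check, and every interval given here is a 95% interval for counting error alone. The libraries of days 0, 8, 13 and 20 held 8902, 11390, 11445 and 10368 barcodes, against a loading target of 10000 cells per sample, and 31850454, 154258012, 120905926 and 149916314 UMIs. The median depth per barcode was 2086 UMIs at day 0 and 13135, 8002 and 11549.5 UMIs in the cultures. After the cell filter and doublet removal 6827, 7174, 8458 and 8417 cells remained.

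The first question was which cells each library held. In the sorted sample AT1-like cells made up 6.84% (467 cells, 6.25 to 7.47) and ciliated-like cells 7.25% (495 cells, 6.65 to 7.89). Most of that library was not epithelial: endothelial-like cells made up 20.1%, lymphoid-like cells 17.1%, myeloid-like cells 15.4%, smooth muscle- and pericyte-like cells 8.31%, mesothelial-like cells 2.08% and mesenchymal-like cells 1.95%. The myeloid-like share of day 0 ranged with the processing from 8.83% at Leiden resolution 0.5 to 31.4% with each library clustered on its own. In the cultures myeloid-like cells were the most numerous class, at 82.6% (5929 cells, 81.7 to 83.5) of day 8, 64.7% (5473 cells, 63.7 to 65.7) of day 13 and 53.5% (4504 cells, 52.4 to 54.6) of day 20, where they were 36.8% with doublets kept and 49.0% with no cell filter. Mesenchymal-like cells made up 8.07%, 14.3% and 34.1% of the same libraries. AT2-like cells, which carry surfactant genes, were 1.22% (83 cells, 0.970 to 1.5) at day 0 and 5.88% (422 cells, 5.35 to 6.45), 6.80% (575 cells, 6.27 to 7.36) and 7.38% (621 cells, 6.83 to 7.96) in the cultures. Airway secretory-like cells were 0.366% (25 cells), 2.16% (155 cells), 10.4% (882 cells) and 3.66% (308 cells). These shares moved with the processing on every day: at Leiden resolution 2.0 they were 0.0146%, 0.572%, 3.04% and 1.70%, with each library clustered on its own 2.20% at day 0 and 4.35% at day 13, and with no cell filter 23.7% at day 13. A Krt13-high basal-like cluster was met at day 13 with 1.73% (146 cells), and other cells with basal keratins were mostly counted as airway secretory-like, in sub-clusters of 323 and 207 cells led by genes such as Krt5 and Krt17. The Krt13-high sub-cluster (135 cells) had Nkx2-1 at 0.941 CPM and Krt8 at 8.47 CPM. The sub-clusters of 323 and 207 cells had Nkx2-1 at 83.1 and 51.0 CPM and Krt8 at 418 and 1165 CPM. For the Krt13-high cells the name basal-like thus rests on the marker list and is not backed by the lung gene Nkx2-1. No cluster passed the naming rule for transitional, neuroendocrine or erythroid cells.

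No cell of days 8 and 20 fell in the AT1-like cluster, and day 13 had 1 such cell. Counting error alone allows shares of up to 0.0514% and 0.0438% in that cluster. The clusters were built from these same genes, so a share moves wherever marker genes differ between days. Cultured cells with AT1 genes were grouped elsewhere: 179 epithelial cells of the cultures, nearly all counted as AT2-like, formed a sub-cluster with Ager at 6730.1 CPM. The naming rule called this sub-cluster AT1 too. It held 7.58, 4.57 and 5.53% of epithelial cells at days 8, 13 and 20, so the shares above do not show that AT1-like cells were absent. AT2-like, airway secretory-like and ciliated-like cells each came from 1 cluster shared by the days. Once epithelial cells were clustered alone, all 495 ciliated-like cells of day 0 lay in a sub-cluster with 1 cell each of days 13 and 20. Myeloid-like cells came mainly from clusters 1, 6 and 9 at day 0 and from clusters 23, 25, 26 and 28 at day 8, 21 at day 13 and 16 and 22 at day 20. Mesenchymal-like cells came mainly from cluster 8 at day 0 and clusters 20, 24, 29 and 30 in culture. A cluster held mostly by 1 library may be that library rather than a cell type. The unnamed share was 19.4%, 0%, 0.236% and 0%, and its main cluster mixed T cell genes such as Trbc2 and Cd3d with the granulocyte genes S100a8, S100a9 and Camp. The sort at day 0, the EpCAM beads at the later days and the depth gap between them all act on these shares.

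**Figure D1:**
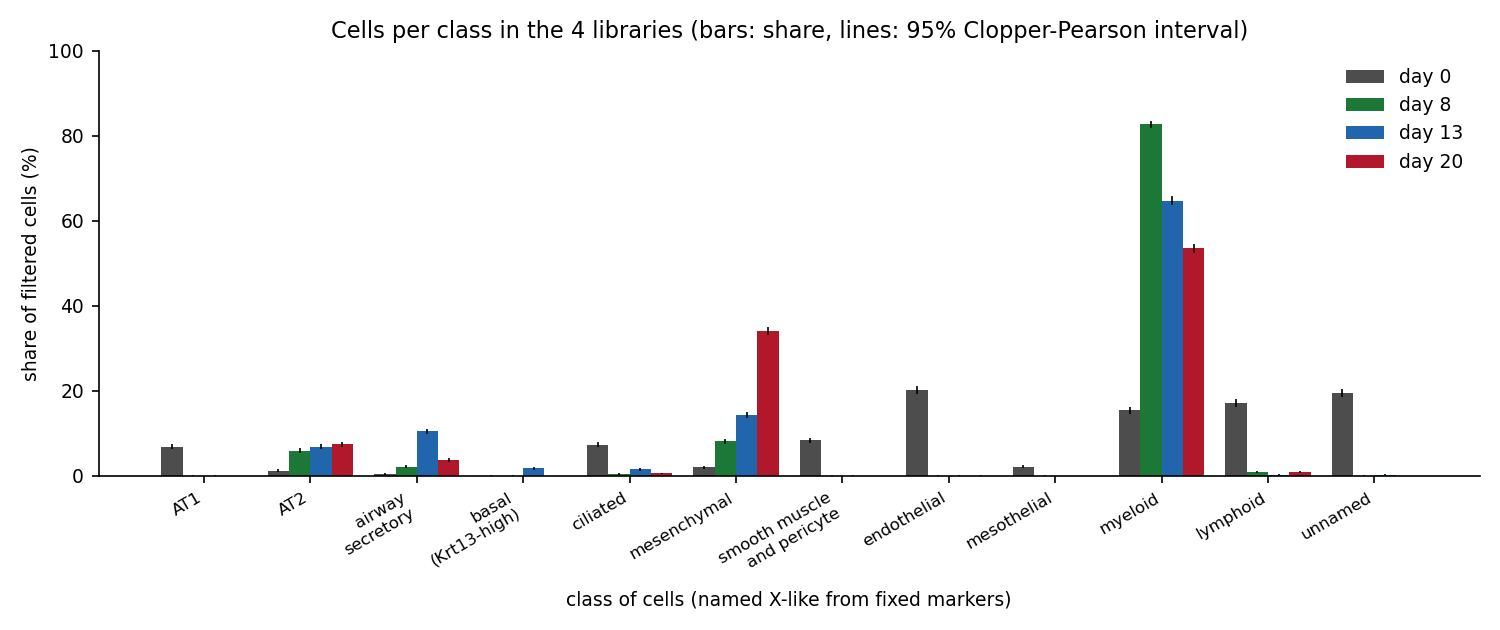
Share of filtered cells in percent (vertical axis) per class of cells (horizontal axis) for the libraries of days 0, 8, 13 and 20, with 95% Clopper-Pearson intervals as lines. Myeloid-like cells took 82.6% of the day 8 library and 53.5% of the day 20 library, and AT1-like cells 6.84% of day 0.

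At day 0 the reporter followed the AT1 class and was not limited to it. AT1-like cells carried EGFP at 1933 CPM (1859 to 2009) and tdTomato at 112 CPM (95.1 to 132). Among cells with at least 2 reporter UMIs, 310 of 372 AT1-like cells were EGFP-dominant, meaning that at least 80% of their reporter UMIs were EGFP. The 83 AT2-like cells of day 0 had EGFP at 1828 CPM (54 of 66 cells EGFP-dominant), ciliated-like cells at 565 CPM (155 of 260) and airway secretory-like cells at 24.0 CPM (0 of 17). The AT2-like result moved when doublets were kept and the cells clustered again: EGFP-dominant cells made up 44.0% instead of 81.8%, and AT2-like cells 4.78% of the library. Under Scrublet's automatic threshold, which called 0 cells at day 0, the AT2-like share of day 0 stayed within the interval of its main value, so kept doublets alone do not account for the move. Endothelial-like cells of the sorted sample had EGFP at 96.7 CPM and tdTomato at 563 CPM, and myeloid-like cells 45.7 and 197 CPM. Gramd2 itself stood at 87.9 CPM (79.7 to 96.7) in the epithelial cells of day 0.

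Day 8 against day 0 asks how epithelial cells in early culture differed from the sorted cells. The AT1 program was lower at day 8. Ager, the receptor for advanced glycation end products and a marker of AT1 cells, was 7297 CPM (7221 to 7375) at day 0 and 877 CPM (859.9 to 894) at day 8, and the homeodomain-only protein gene Hopx was 5321 CPM (5256 to 5387) and 323 CPM (313 to 334). Surfactant genes were higher: Sftpc, which encodes surfactant protein C, was 11334 CPM (11238 to 11429.9) and 64344 CPM (64200.5 to 64488), and Sftpb 906 CPM (879 to 933) and 5465 CPM (5423 to 5507). The proliferation gene Mki67 was 1.05 CPM (0.341 to 2.45) at day 0 and 104 CPM (98.0 to 109.6) at day 8. In all, 912 genes were at least 2-fold higher and 2021 at least 2-fold lower among 7321 genes with at least 20 CPM in either library. Of the epithelial cells of day 0, 43.6% were AT1-like and 46.3% ciliated-like, so every ratio against day 0 also carries that mix of classes.

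The genes with the largest ratios in favour of day 8 were the kallikreins Klk13, 553-fold (log2 ratio 9.11, interval 7.84 to 12.74, 2 UMIs on the lower side), and Klk10, 430.0-fold (log2 ratio 8.75, interval 7.20 to 11.03, 3 UMIs on the lower side), where a side with fewer than 3 UMIs is taken at the floor of 3. They were followed by Phgr1 214-fold, the basal keratin Krt5 at least 202-fold, the cornified envelope gene Sprr1a at least 154-fold and arginase 1, Arg1, 154-fold (log2 ratio 7.27, interval 6.37 to 14.16, 1 UMI on the lower side). Mesothelin, Msln, was 151-fold higher, the survivin gene Birc5 142-fold, the oxygen sensor Egln3 at least 139.8-fold and Tmem213 138-fold. The secreted airway protein gene Bpifa1 was 122-fold higher and the keratin Krt15 118-fold. In favour of day 0, the cytochrome P450 gene Cyp2a5 led at 1011-fold, then the AT1 genes Rtkn2 858-fold, Igfbp2 769-fold and Spock2 517-fold. Also lower at day 8 were the neurotrophin Bdnf at least 531-fold, Gpm6a at least 391-fold, Cped1 343-fold and Fxyd1 at least 254-fold, the cytochrome Cyp2b10 179.6-fold, T2 169-fold and Pxdc1 161-fold, and the secreted Wnt inhibitor Wif1 126-fold.

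Among the fixed cell type lists, AT1 markers had 0 higher and 13 lower of 14 measured members (median log2 ratio -3.89), at percentile 0 of random lists matched on expression. Of 15 AT2 markers, 8 were higher and 1 lower (median 1.13), with the lysozyme Lyz1 10.6-fold, the lung chemokine Cxcl15 10.2-fold and the protease Napsa 7.71-fold. Transitional markers had 7 higher and 2 lower of 14, median 0.92, with Clu 13.6-fold, Cldn4 8.46-fold and Sfn 5.13-fold. Cycling markers had 12 higher and 0 lower of 12, median 5.84, among them Mki67 98.6-fold, Cdk1 86.3-fold and Ube2c 70.3-fold. Basal markers had 3 higher and 0 lower of 8, median 4.88. Airway secretory markers went both ways, 5 higher and 4 lower of 12, median 1.39: Reg3g 55.1-fold and Agr2 37.7-fold were higher, while Scgb1a1, the club cell secretoglobin, was 159475 CPM (159116 to 159834) at day 0 and 14923 CPM (14854 to 14992) at day 8. All 10 ciliated markers were lower (median -3.27), with Tmem212 48.2-fold, Sec14l3 21.6-fold and Tppp3 14.4-fold. Neuroendocrine markers had 0 higher and 3 lower of 4, median -2.90, mesothelial markers 2 higher and 1 lower of 3, median 5.25, lymphoid markers 0 higher and 1 lower of 5, median -4.60 and endothelial markers 0 higher and 0 lower of 5, median -3.98.

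Metabolic genes were higher together at day 8. Of the glycolysis and hypoxia list 10 of 13 members were higher and 0 lower (median 2.01, percentile 100), with Pgk1 15.1-fold, Ldha 11.3-fold and Gapdh 10.3-fold. Cholesterol synthesis had 10 higher and 0 lower of 12, median 1.87, with Cyp51 8.96-fold, Fdps 6.97-fold and Idi1 5.73-fold, and fatty acid synthesis 7 higher and 0 lower of 11, median 1.3, with Elovl6 25.9-fold and Scd1 16.9-fold. The surfactant and lamellar body list had 5 higher and 1 lower of 10, median 1.36. S phase genes had 8 higher and 0 lower of 14, median 2.85, with Mcm5 17.3-fold. The caveolae and vascular crosstalk list of AT1 cells had 0 higher and 11 lower of 11, median -2.48, led by Sema3e 28.7-fold, Cav1 28.4-fold and Vegfa 16.2-fold. Basement membrane genes had 0 higher and 8 lower of 10, median -1.59, with the laminin Lama3 39.5-fold and the collagen Col4a3 36.2-fold. YAP/TAZ targets had 0 higher and 6 lower of 11, median -1.63, with Ccn2 5.57-fold, and Notch pathway genes 0 higher and 5 lower of 9, median -1.36, with Jag1 10.7-fold.

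MHC class II genes had 0 higher and 3 lower of 7, median -1.19, with H2-Aa 4.49-fold and H2-Eb1 4.04-fold. The interferon response had 1 higher and 5 lower of 11, median -1.78, with Usp18 31.4-fold and Ifit3 12.8-fold, and the NF-kB and chemokine list 5 higher and 1 lower of 11, median 0.86, with the neutrophil attractant Cxcl1 48.1-fold and lipocalin 2, Lcn2 8.95-fold. Epithelial junction genes had 0 higher and 6 lower of 12, median -0.60, with Cldn18 7.80-fold, Ocln 4.27-fold and Cdh1 3.75-fold, and lung transcription factors 1 higher and 4 lower of 12, median -0.57, with Tead1 4.39-fold, Gata6 2.66-fold and Nkx2-1 2.31-fold. The remaining lists were p53 targets with 4 higher and 2 lower of 12, median 0.74, TGF-beta targets with 2 higher and 3 lower of 9, median -0.90, FGF/EGF feedback with 3 higher and 0 lower of 10, median 0.56, NRF2 targets with 2 higher and 0 lower of 10, median 0.13, Wnt targets with 2 higher and 1 lower of 6, median -1.22 and immediate early and heat shock genes with 1 higher and 3 lower of 13, median -0.52. The gastrointestinal list and the smooth muscle and pericyte list had 1 and 2 detected members and no median, and the erythroid list had 0.

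Some genes of other cell types were also higher among the epithelial cells of day 8. Myeloid markers had 6 higher and 2 lower of 13, median 0.10, with the scavenger receptor Marco 19.6-fold and the lysosomal Cd68 10.8-fold, and mesenchymal markers 1 higher and 1 lower of 7, median 1.78, with decorin, Dcn 27.3-fold. The epithelial-mesenchymal transition list had 3 higher and 0 lower of 7, median 2.52, with Fn1 13.0-fold, S100a4 8.19-fold and Vim 6.88-fold. Without the sub-clusters led by myeloid or mesenchymal genes (172 and 29 cells of all days), which were set aside after seeing the data, Marco was 7.64-fold, Cd68 4.35-fold, Vim 2.37-fold and S100a4 4.03-fold higher, and the gene counts were 867 higher and 1983 lower.

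**Figure D2:**
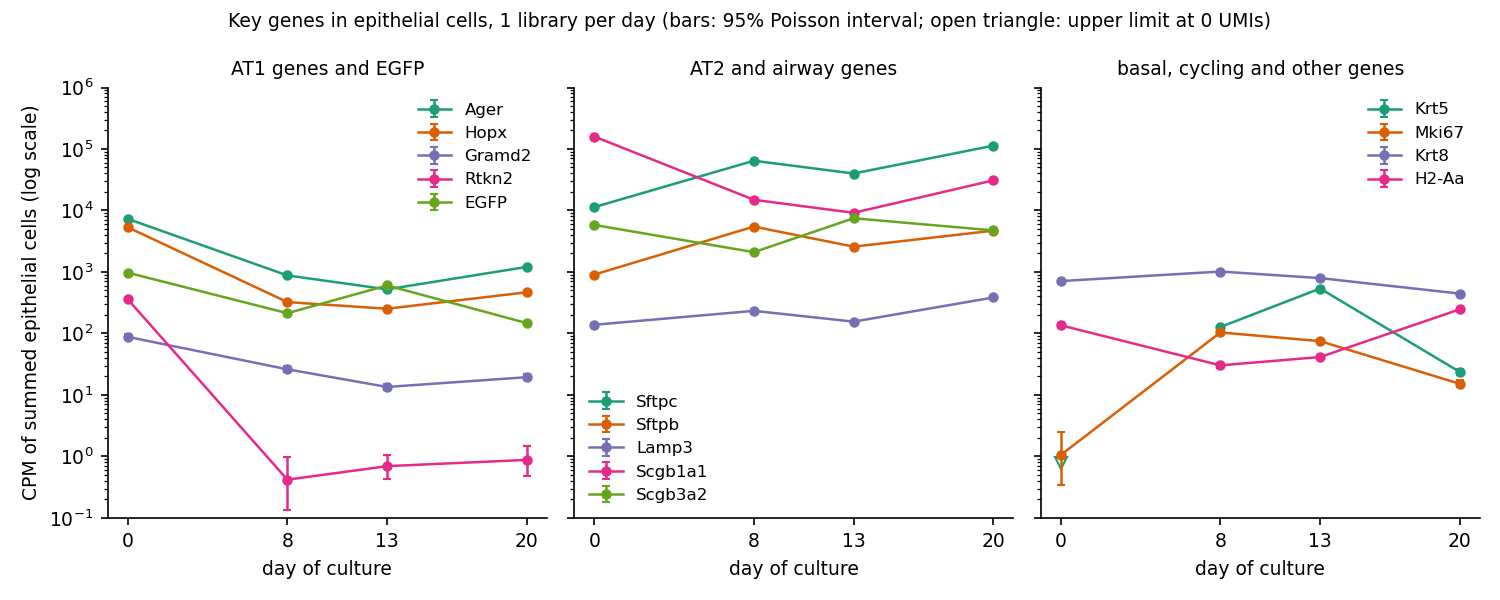
CPM of summed epithelial cells on a log scale (vertical axes) against day of culture (horizontal axes) for AT1 genes and EGFP, AT2 and airway genes, and basal, cycling and other genes, with 95% Poisson intervals as bars and an open triangle for the upper limit where no UMI was seen. Ager was 7297 CPM at day 0 and 1207 CPM at day 20, and Sftpc 11334 and 113235 CPM.

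Day 13 against day 8 asks what differed in the middle of the culture. The classes mixed in the epithelial cells differed too: at days 8, 13 and 20 AT2-like cells were 69.5, 33.3 and 63.6% of them, airway secretory-like cells 25.5, 51.0 and 31.6% and Krt13-high cells 0, 8.45 and 0%, so ratios of this step and the next also carry that mix. The largest ratios came from genes of the Krt13-high cluster. The keratinocyte gene Krtdap was at least 1480.0-fold higher, the galectin Lgals7 959-fold (log2 ratio 9.91, interval 9.01 to 16.79, 1 UMI on the lower side), the suprabasal keratin Krt13 769-fold, the late cornified envelope genes Lce3f at least 388-fold, Lce3a at least 304-fold and Lce3e at least 282-fold, the keratin Krt16 at least 296-fold and the metallothionein Mt4 at least 294-fold. Genes lower at day 13 included the chemokine Cxcl2 6.07-fold, the hypoxia-responsive Ankrd37 5.0-fold, Phgr1 4.61-fold and Retnlg 4.33-fold, the airway gene Bpifb1 3.56-fold, the lactate transporter Slc16a3 3.49-fold, the chemokine Ccl2 3.49-fold and Ly6k 3.38-fold. In total 218 genes were at least 2-fold higher and 92 lower among 5925. The Krt13-high cluster (146 cells, all of day 13) holds keratin genes that also define it. Without it, a choice made after seeing the data, Krt13 was 7.94-fold and Krt16 at least 2.98-fold higher, and the counts were 186 and 76.

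Basal markers had 6 higher and 0 lower of 8, median 3.03, with Krt6a 16.0-fold, Krt14 13.4-fold, Krt17 9.77-fold and Krt5 4.22-fold, and without the Krt13-high cluster these were 1.74-fold, 3.46-fold, 5.08-fold and 3.64-fold higher. NRF2 targets, which respond to oxidative stress, had 4 higher and 0 lower of 10, median 0.96, with the glutathione genes Gclm 2.58-fold, Gsta4 2.29-fold and Gclc 2.18-fold. AT2 markers had 0 higher and 2 lower of 15, median -0.64 and the surfactant list 1 higher and 2 lower of 10, median -0.70, with Sftpb 2.12-fold and Scd1 2.47-fold. The NF-kB and chemokine list had 0 higher and 3 lower of 11, median -0.22, with Cxcl1 5.41-fold and Cxcl5 3.20-fold, and immediate early and heat shock genes 2 higher and 3 lower of 13, median -0.18, with Fosb 2.36-fold, Fos 2.33-fold and Dusp1 2.27-fold. AT1 markers had 1 higher and 0 lower of 14, median -0.34, transitional markers 1 higher and 0 lower of 14, median -0.01, airway secretory markers 3 higher and 2 lower of 12, median -0.25, ciliated markers 1 higher and 0 lower of 10, median 0.90 and cycling markers 0 higher and 0 lower of 12, median -0.45. Glycolysis and hypoxia had 0 higher and 1 lower of 13, median -0.64, MHC class II 0 higher and 0 lower of 7, median 0.35, the interferon response 1 higher and 0 lower of 11, median 0.60 and basement membrane genes 0 higher and 2 lower of 10, median -0.40. The lung transcription factors Foxa2 and Cebpa were 2.20-fold and 2.11-fold lower. Scgb3a2, a secretoglobin of distal airways, was 3.57-fold higher and EGFP 2.83-fold. Myeloid markers had 3 higher and 1 lower of 13, median 0.30, with S100a9 at least 144-fold and the complement gene C1qa 6.13-fold. The Krt13-high sub-cluster of day 13 scored highest for basal markers (4.91) and next for myeloid markers (1.44). The S100a9 ratio may therefore come partly from it and is not read as neutrophil RNA.

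Day 20 against day 13 asks what differed at the end of the culture. MHC class II genes were higher and cycling markers lower. The MHC class I gene H2-Q7 was 15.4-fold higher, the interferon-inducible GTPase genes Gbp2b 14.1-fold, Iigp1 11.6-fold and Igtp 10.3-fold, then Ankrd37 7.74-fold, the secreted peroxidase Gpx3 6.41-fold and the MHC class II gene H2-Aa 5.97-fold. H2-Q7, Gbp2b, Iigp1, Igtp and H2-Aa were among the leading genes of an AT2-named sub-cluster of 127 cells. It held 11.8% of epithelial cells at day 20 and 0.694% at day 13. Iigp1 was 1176 CPM there and at most 34.8 CPM in any other epithelial sub-cluster. H2-Ab1 was less confined, at 691 CPM there and 525 CPM in an AT2-named sub-cluster of 208 cells. Ratios of these genes and of the MHC class II and interferon lists may thus also carry that sub-cluster. On the lower side stood Krt13 3078-fold and Krtdap at least 1976-fold, Lgals7 1280.0-fold (log2 ratio -10.32, interval -13.95 to -9.05, 2 UMIs on the lower side) and Cnfn at least 1007-fold, Krt6a at least 739.8-fold, Lce3f at least 517-fold, Lce3a at least 406-fold and Krt16 at least 395-fold. A total of 189 genes were at least 2-fold higher and 374 lower among 5975, or 33.6% higher, and under median-of-ratios scaling 44.3% were higher (249 against 313). Without the Krt13-high cluster Krt13 was 31.8-fold lower and the counts were 158 and 325.

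MHC class II genes had 6 higher and 0 lower of 7, median 2.43 at percentile 100, with H2-Eb1 5.49-fold and H2-Ab1 5.39-fold, and the interferon response had 3 higher and 0 lower of 11, median 0.76, with Ifit3 3.60-fold and Ifit1 3.50-fold. AT2 markers had 6 higher and 0 lower of 15, median 0.94, with complement Hc 4.25-fold, the calcium-binding S100g 3.94-fold, the phosphate transporter Slc34a2 2.84-fold and Sftpc 2.84-fold and Lamp3 2.47-fold, and the surfactant list 7 higher and 0 lower of 10, median 1.28. AT1 markers had 2 higher and 0 lower of 14, median 0.47, with Vegfa 2.43-fold and Ager 2.32-fold. All 12 cycling markers were lower (median -2.18), with Rrm2 5.34-fold, Pclaf 5.27-fold and Mki67 4.94-fold, and S phase had 0 higher and 9 lower of 14, median -1.54. Transitional markers had 0 higher and 6 lower of 14, median -0.97, with Sfn 5.62-fold, Plaur 3.99-fold and Cldn4 2.48-fold. Basal markers had 0 higher and 5 lower of 8, median -5.46, with Krt17 394-fold, Krt14 365-fold and Krt5 22.8-fold. The Krt13-high sub-cluster, all of day 13, had Krt14 at 2823 CPM and Sfn at 2750 CPM, against at most 271 and 374 CPM in any other epithelial sub-cluster. The ratios of Krt14 and Sfn thus also carry that sub-cluster.

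In the same comparison airway secretory markers had 2 higher and 3 lower of 12, median -0.15, with Agr2 6.16-fold and Scgb3a1 4.23-fold while Scgb1a1 3.37-fold was higher, and ciliated markers 0 higher and 3 lower of 10, median -0.78. Immediate early and heat shock genes had 0 higher and 4 lower of 13, median -0.31, with the chaperones Hspa1a 6.51-fold and Hspa1b 5.28-fold. NRF2 targets had 0 higher and 2 lower of 10, median -0.65, with the cystine transporter Slc7a11 5.10-fold and Gstp1 6.89-fold. YAP/TAZ targets had 0 higher and 2 lower of 11, median -0.05 and myeloid markers 0 higher and 3 lower of 13, median -0.96. The lung transcription factor Cebpa was 2.43-fold higher, desmoplakin, Dsp, 2.86-fold lower, and EGFP 4.10-fold lower.

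Across the whole culture, day 20 against day 0, 648 genes were at least 2-fold higher and 1885 lower among 7147. AT1 markers had 0 higher and 13 lower of 14, median -3.24, with Igfbp2 2052-fold, Spock2 552-fold, Rtkn2 409-fold, Hopx 11.4-fold, Ager 6.05-fold and Gramd2 4.53-fold, and EGFP was 6.61-fold lower. AT2 markers had 11 higher and 0 lower of 15, median 1.51, with Napsa 12.1-fold, Sftpc 9.99-fold, Cxcl15 9.43-fold and Sftpb 5.18-fold. Airway secretory markers had 5 higher and 2 lower of 12, median 0.89, with the antimicrobial lectin Reg3g 112-fold and Bpifa1 81.8-fold, and the basal genes Krt15 161-fold and Trp63 48.8-fold (log2 ratio 5.61, interval 4.33 to 9.24, 2 UMIs on the lower side) were higher too. Glycolysis and hypoxia had 9 higher and 0 lower of 13, median 1.59, cholesterol synthesis 9 higher and 0 lower of 12, median 1.22 and fatty acid synthesis 5 higher and 0 lower of 11, median 1.28. Caveolae and vascular crosstalk had 0 higher and 11 lower of 11, median -2.39, basement membrane genes 0 higher and 8 lower of 10, median -2.14, YAP/TAZ targets 0 higher and 7 lower of 11, median -1.5 and ciliated markers 0 higher and 10 lower of 10, median -3.15. MHC class II had 3 higher and 0 lower of 7, median 1.05 and mesenchymal markers 4 higher and 1 lower of 7, median 5.14, with Dcn 71.9-fold. The median log2 ratio of all genes with at least 20 CPM in both libraries was -0.10, 0.04, -0.11 and -0.17 for day 8 against 0, 13 against 8, 20 against 13 and 20 against 0, and the ratios above are not corrected for it.

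Within AT2-like cells (83, 422, 575 and 621 cells, median depth 4027, 11993, 13566 and 14081 UMIs) AT2 markers as a list were lower at day 8 and day 20 than at day 0, the opposite of their direction over all epithelial cells. Sftpc was 132679, 106666, 134874 and 191886 CPM at days 0, 8, 13 and 20, and Lamp3, of lamellar body membranes, 1617, 366, 518 and 645 CPM. AT2 markers at day 8 against day 0 had 0 higher and 9 lower of 15, median -1.16 and at day 20 against day 0 0 higher and 8 lower of 15, median -1.03. MHC class II genes were lower at day 8, with 0 higher and 7 lower of 7, median -3.99, and higher at each later step, with 4 higher and 0 lower of 7, median 1.05 and then 5 higher and 0 lower of 7, median 1.56. The invariant chain Cd74 was 4026, 429.9, 971 and 2012 CPM. Transitional markers were higher at day 8, with 9 higher and 0 lower of 14, median 1.54: Clu was 84.7, 822, 526 and 372 CPM and Cldn4 2.49, 55.9, 31 and 7.17 CPM. Glycolysis and hypoxia had 11 higher and 0 lower of 13, median 2.80 at day 8 and 11 higher and 1 lower of 13, median 2.32 at day 20 against day 0, and the lactate dehydrogenase gene Ldha was 247, 2913, 1768 and 1306 CPM. Ager stood at 1166, 1387, 1723 and 1738 CPM. AT1-named sub-clusters held 3, 46, 78 and 54 of the 83, 422, 575 and 621 AT2-like cells. The myeloid-named sub-cluster held 18, 40 and 15 of those of days 8, 13 and 20. At day 20, 113 of 621 lay in the AT2-named sub-cluster of 127 cells led by interferon-inducible genes. The levels and lists of this class carry that mix. Of the day 0 cells 76 of 83 lay in a sub-cluster that held 17, 53 and 62 AT2-like cells of days 8, 13 and 20, so the differences from day 0 also carry a change of sub-cluster.

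Cycling markers of AT2-like cells had 12 higher and 0 lower of 12, median 2.93 at day 8, 0 higher and 9 lower of 12, median -1.05 at day 13 and 0 higher and 8 lower of 12, median -1.93 at day 20 against the sample before, and Mki67 was 0, 67, 32.7 and 6.63 CPM. Immediate early and heat shock genes had 0 higher and 6 lower of 13, median -0.86 at day 20 against day 13, and the interferon response 5 higher and 0 lower of 9, median 1.91 at day 20 against day 0. Myeloid markers were higher in AT2-like cells of day 8 too, with 6 higher and 0 lower of 10, median 2.81. Myeloid-like cells were 82.6% of that library and 15.4% of day 0, and 18 of its 422 AT2-like cells lay in the myeloid-named sub-cluster. The floor at day 0 was 7.47 CPM. Free RNA and such cells may add to these ratios, which are not read as expression by AT2-like cells. Gene counts within AT2-like cells were 809 higher and 1019 lower for day 8 against day 0, 46 and 86 for day 13 against day 8, 84 and 140 for day 20 against day 13, and 482 and 1004 for day 20 against day 0.

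**Figure D3:**
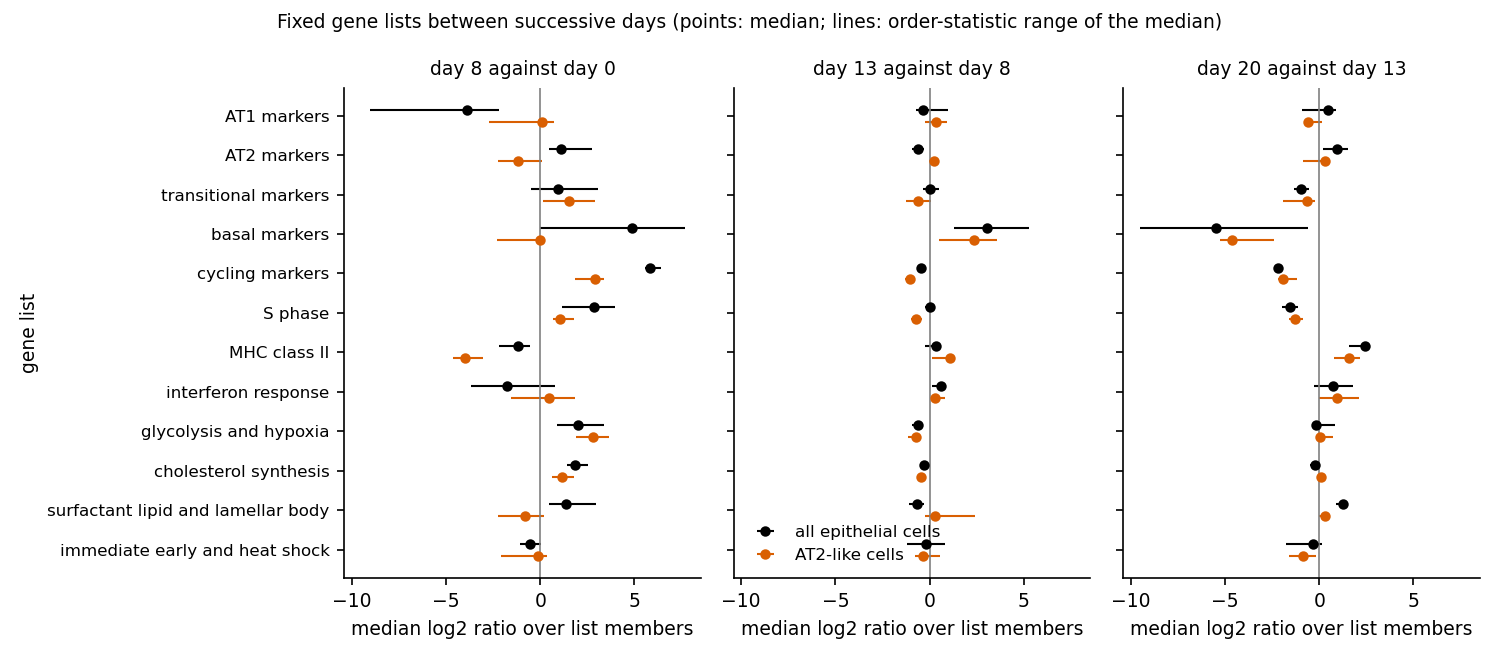
Median log2 ratio over list members (horizontal axes) for 12 fixed gene lists (vertical axis) and each successive pair of days, in all epithelial cells (black) and in AT2-like cells (orange), with lines for the order-statistic range of the median. AT2 markers at day 8 against day 0 had a median of 1.13 over epithelial cells and -1.16 within AT2-like cells.

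Airway secretory-like cells were compared among days 8, 13 and 20, since day 0 held 25 of them. Their cluster had Krt15, Krt5 and Scgb3a2 among its leading genes, and its make-up differed between days: basal-named sub-clusters held 42, 466 and 13 of its 155, 882 and 308 cells and AT2-named ones 60, 9 and 8. The values that follow carry that mix. Krt5 was 391, 831 and 65.0 CPM and Krt15 612, 2363 and 780.4 CPM at the 3 days, while Scgb1a1 was 15424, 3253 and 33052 CPM. Basal markers had 4 higher and 0 lower of 8, median 1.33 at day 13 against day 8 and 0 higher and 6 lower of 8, median -3.52 at day 20 against day 13. In the latter comparison all 12 cycling markers were lower (median -1.95), S phase had 0 higher and 11 lower of 14, median -1.35, MHC class II 4 higher and 0 lower of 6, median 2.62 and AT1 markers 5 higher and 0 lower of 12, median 1.34, with Ager at 102, 21.0 and 528 CPM. The chemokine Cxcl1 was 75.6, 5.94 and 1.09 CPM. The gene counts were 116 higher and 118 lower at day 13 against day 8, and 264 and 258 at day 20 against day 13.

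Myeloid-like cells, held by largely different clusters on each day as named above, showed the resident alveolar macrophage genes Chil3 at 9630.4, 6.02, 1.49 and 0.0420 CPM and Ear2 at 1449, 64.0, 44.4 and 16.2 CPM for days 0, 8, 13 and 20. The complement gene C1qa was 140.2, 257, 1694 and 2419 CPM and C1qb 151, 1611, 5898 and 5777 CPM. MHC class II genes had 0 higher and 6 lower of 7, median -5.31 at day 8 against day 0, 6 higher and 0 lower of 7, median 4.47 at day 13 against day 8 and 7 higher and 0 lower of 7, median 2.81 at day 20 against day 13, and H2-Ab1 was 384, 3.80, 154 and 1081 CPM. Cycling markers had 12 higher and 0 lower of 12, median 2.61 at day 8 and 0 higher and 12 lower of 12, median -2.38 at day 13. The interferon response had 10 higher and 0 lower of 12, median 2.98 at day 20 against day 0, with Ifit3 at 4.87, 16.2, 73.6 and 203 CPM. Counts of genes at least 2-fold apart were 734 and 1343, 247 and 380, 102 and 48, and 797 and 1296, higher and lower, for day 8 against 0, 13 against 8, 20 against 13 and 20 against 0.

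Mesenchymal-like cells of the cultures (mainly clusters 20, 24, 29 and 30) were set against those of the sorted lung (mainly cluster 8), in a medium that held fibroblasts of a line and an inhibitor of TGF-beta receptors. TGF-beta targets had 0 higher and 10 lower of 11, median -3.36 at day 8 and 0 higher and 10 lower of 11, median -3.54 at day 20 against day 0. The connective tissue growth factor Ccn2 was 896, 1.45, 1.04 and 1.98 CPM, the actin-binding Tagln 682, 8.01, 15.1 and 12.1 CPM and the collagen Col1a1 1621, 481, 580.3 and 708 CPM. Cycling markers had 12 higher and 0 lower of 12, median 3.52 and immediate early and heat shock genes 0 higher and 12 lower of 13, median -2.51 at day 8 against day 0. The reporter tdTomato was 146, 4.43, 4.94 and 1.96 CPM. Transcripts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were 131, 1.36, 2.03 and 0.910 CPM. The cultured cells may thus be mainly the MLg feeder line. The ratios against day 0 may then set a cell line against lung cells and are not read as a change in lung mesenchyme. The counts were 1146 higher and 2213 lower at day 8 against day 0, 72 and 19 at day 13 against day 8, 47 and 38 at day 20 against day 13, and 1196 and 2284 at day 20 against day 0. Lymphoid-like cells, from clusters 4, 10 and 14 at day 0 and mainly 14 in culture, had 551 and 414 at day 8 against day 0 and 670 and 1053 at day 20 against day 0.

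Among AT2-like cells with at least 2 reporter UMIs, day 8 had 58 EGFP-dominant, 128 tdTomato-dominant and 100 between, day 13 107 EGFP-dominant, 217 tdTomato-dominant and 102 between and day 20 81 EGFP-dominant, 153 tdTomato-dominant and 97 between. The EGFP-dominant share was 20.3% (15.8 to 25.4), 25.1% (21.1 to 29.5) and 24.5% (19.9 to 29.5), and it depends on the UMI minimum: with at least 8 reporter UMIs, chosen after seeing the data, it was 44.0%, 52.3% and 71.2% at days 8, 13 and 20. That minimum counts both reporters together, so it selects by reporter level as well as by depth. At day 13 EGFP was 2112 CPM in a sub-cluster with 125 of 126 cells EGFP-dominant, and tdTomato 201 CPM in the Krt13-high sub-cluster. The higher shares are therefore not read as better estimates of the labelled share. Airway secretory-like cells had 3 EGFP-dominant, 83 tdTomato-dominant and 36 between at day 8, 313 EGFP-dominant, 347 tdTomato-dominant and 88 between at day 13 and 1 EGFP-dominant, 163 tdTomato-dominant and 59 between at day 20, and with at least 8 reporter UMIs 71.8% of day 13 were EGFP-dominant. Ciliated-like cells had 5 EGFP-dominant, 7 tdTomato-dominant and 10 between, 53 EGFP-dominant, 27 tdTomato-dominant and 32 between and 0 EGFP-dominant, 18 tdTomato-dominant and 16 between. None of the 81 Krt13-high cells with enough UMIs was EGFP-dominant, and 73 were tdTomato-dominant. Other basal-named cells of day 13, mostly counted as airway secretory-like, did hold EGFP-dominant cells. In the sub-clusters of 323 and 207 cells led by Krt5 and Krt17 these were 121 of 245 and 46 of 144 at day 13. EGFP in AT2-like cells was 1828, 294, 413 and 224 CPM and tdTomato 109.6, 149, 173 and 100 CPM at days 0, 8, 13 and 20. The sub-clusters that hold AT2-like cells differed at day 20. EGFP-dominant cells were 39 of 51, 18 of 84, 8 of 99, 2 of 37, 0 of 20 and 0 of 1 in the AT2-named sub-clusters of 208, 127, 301, 308, 445 and 111 cells. In the AT1-named sub-cluster of 179 cells they were 10 of 25. The class shares thus average over unlike sub-clusters. Levels and counts are of transcripts, which free RNA in droplets adds to: EGFP was 2.05, 3.20 and 0.942 CPM in mesenchymal-like and 10.4, 11.3 and 6.32 CPM in myeloid-like cells of days 8, 13 and 20.

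**Figure D4:**
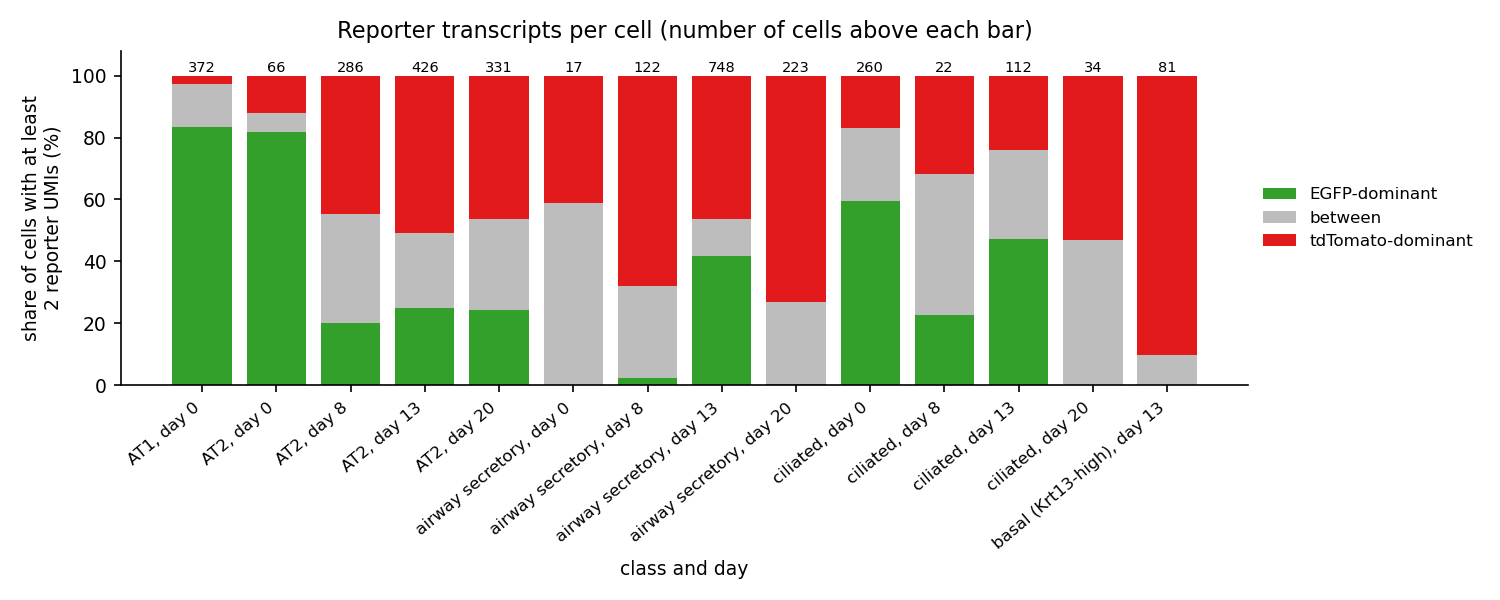
Cells with at least 2 reporter UMIs by range, in percent (vertical axis), for each class and day (horizontal axis), with the number of cells above each bar. EGFP-dominant cells made up 83.3% of AT1-like cells at day 0, 24.5% of AT2-like cells at day 20 and 41.8% of airway secretory-like cells at day 13.

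With each cell thinned to 2000 UMIs, an Ager UMI was seen in 50.6, 59.1, 28.5 and 65.7% of epithelial cells at days 0, 8, 13 and 20, against 4.07, 0.856, 1.68 and 0.850% of myeloid-like cells, which should lack it. The shares without thinning were 56.9, 79.7, 40.9 and 84.3%. The day 8 and day 20 shares lie above that of day 0 while the CPM lies below it, so no order is read from them. Hopx was seen in 71.8, 26.2, 22.2 and 39.3% (myeloid-like 12.3, 0.856, 0.736 and 0.551%), Gramd2 in 19.1, 6.15, 2.95 and 3.57% (myeloid-like 0, 0.0510, 0.0750 and 0.0230%), and EGFP in 61.8, 17.4, 30.8 and 14.6% (myeloid-like 8.41, 2.33, 2.28 and 1.29%). A Sftpc UMI was seen in 27.9, 87.5, 67.2 and 78.5% of epithelial and 14.2, 50.5, 68.4 and 48.5% of myeloid-like cells, so the day 13 share is at background. Thinning kept 786, 585, 1661 and 924 epithelial cells and left out 284, 22, 67 and 52, with median depths of 3816, 15530.0, 15025 and 14868 UMIs, against 5281, 16920.0, 7859 and 10126 UMIs for myeloid-like cells. Scgb1a1 shows the level free RNA can reach, since in the sorted sample it was seen in 98.2% of myeloid-like cells.

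The positions of the main genes, each protein-coding, are given on mouse assembly GRCm38 in the GENCODE vM21 annotation. Ager (ENSMUSG00000015452) lies on chromosome 17 from 34597862 to 34600936 on the plus strand. Gramd2 (ENSMUSG00000074259) lies on chromosome 9 from 59680144 to 59718874 on the plus strand. Hopx (ENSMUSG00000059325) lies on chromosome 5 from 77086988 to 77115121 on the minus strand. Rtkn2 (ENSMUSG00000037846) lies on chromosome 10 from 67979570 to 68059740 on the plus strand. Sftpc (ENSMUSG00000022097) lies on chromosome 14 from 70520949 to 70524081 on the minus strand. Scgb1a1 (ENSMUSG00000024653) lies on chromosome 19 from 9083636 to 9087958 on the minus strand. Scgb3a2 (ENSMUSG00000038791) lies on chromosome 18 from 43764289 to 43767399 on the plus strand. Krt5 (ENSMUSG00000061527) lies on chromosome 15 from 101707070 to 101712898 on the minus strand. Krt13 (ENSMUSG00000044041) lies on chromosome 11 from 100117327 to 100121566 on the minus strand. Mki67 (ENSMUSG00000031004) lies on chromosome 7 from 135689784 to 135716361 on the minus strand. Klk13 (ENSMUSG00000054046) lies on chromosome 7 from 43712567 to 43727534 on the plus strand. Cyp2a5 (ENSMUSG00000005547) lies on chromosome 7 from 26835305 to 26843548 on the plus strand. H2-Aa (ENSMUSG00000036594) lies on chromosome 17 from 34282744 to 34287823 on the minus strand.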

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

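The barcodes that failed the cell filter enter the results above only in the shares given with no cell filter. Those of a fixed set of key genes at 2-fold or more their level in kept cells are given here. The comparison was set after seeing the data, and no biological or technical explanation was tested. At day 0, 1552 barcodes were left out. In them Sftpc was 5140.1 CPM against 2256 CPM in kept cells, and Lamp3 was 112 CPM against 27.1 CPM in kept cells. At day 8 (3497 barcodes) Ager was 197 CPM against 82.1 CPM in kept cells, Gramd2 was 9.06 CPM against 2.49 CPM in kept cells, Lamp3 was 79.8 CPM against 23.4 CPM in kept cells, and Col1a1 was 267 CPM against 49.5 CPM in kept cells. At day 13 (2134 barcodes) Gramd2 was 9.79 CPM against 4.26 CPM in kept cells. At day 20 (1190 barcodes) Ager was 351 CPM against 148 CPM in kept cells, Gramd2 was 11.6 CPM against 2.57 CPM in kept cells, and Lamp3 was 135 CPM against 47.8 CPM in kept cells. In the same day 20 barcodes Scgb3a2 was 1633 CPM against 609 CPM in kept cells, Col1a1 was 1344 CPM against 375 CPM in kept cells, and Epcam was 84.5 CPM against 41.4 CPM in kept cells.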

How the results depend on the processing

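The alternatives that leave out sub-clusters or the Krt13-high cluster, and those for the reporter ranges, were chosen after seeing the data. The others were planned. No paired analysis was possible because each day has 1 library and no result comes from a test. Values that stayed within the interval of the main value, or for gene counts within 1.5 times, numbered 63 of 80 for gene counts, 745 of 812 for list medians over epithelial cells, 337 of 348 for those within AT2-like cells, 3409 of 4816 for named genes, 214 of 329 for class shares, 63 of 168 for shares of cells with a UMI and 27 of 45 for EGFP-dominant shares. No list median and no gene count moved that far under median-of-ratios scaling. Without the sub-clusters led by myeloid or mesenchymal genes no list median over epithelial cells did. The cause of the values that follow was not tested, except that a higher CPM minimum leaves fewer genes to count and a lower one more. In epithelial and AT2-like cells depth limits day 0 most, with a floor of 0.631 CPM for 3 counts over epithelial cells and 7.47 CPM within AT2-like cells. In lymphoid-like cells the floor was 0.749 CPM at day 0 and 13.5 and 4.88 CPM at days 8 and 20.

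Under a minimum of 5 CPM the counts of genes at least 2-fold apart were, for day 8 against day 0 1480 higher, day 13 against day 8 545 higher and 184 lower, day 20 against day 13 346 higher and 884 lower, day 20 against day 0 1117 higher. Under a minimum of 100 CPM the counts of genes at least 2-fold apart were, for day 8 against day 0 348 higher and 516 lower, day 13 against day 8 58 higher and 25 lower, day 20 against day 13 61 higher and 77 lower, day 20 against day 0 240 higher and 504 lower. Over all filtered cells the counts of genes at least 2-fold apart were, for day 13 against day 8 481 higher and 372 lower, day 20 against day 13 192 lower. Over all filtered cells, where myeloid-like and mesenchymal-like cells dominate, the following list medians had the opposite sign of that over epithelial cells, for day 8 against day 0 surfactant lipid and lamellar body at -0.12, for day 13 against day 8 AT2 markers at 1.02, surfactant lipid and lamellar body at 0.69 and basement membrane at 1.01, for day 20 against day 13 AT2 markers at -0.38, cycling markers at 0.31, surfactant lipid and lamellar body at -0.00490, S phase at 0.25 and fatty acid synthesis at -0.13, for day 20 against day 0 MHC class II at -1.43. With the same cells the median of AT2 markers for day 8 against day 0 kept its sign and lay outside the range of the main value, at 0.0773.

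With the mean over cells the log2 ratio for day 8 against day 0 turned sign for Scgb3a2 0.86. Over all filtered cells the log2 ratios of opposite sign for day 8 against day 0 were Clu -0.52, Dcn -0.63, Fn1 -2.77, Lcn2 -0.30, Msln -1.80, Napsa -0.23 and Upk1b -2.00. Over all filtered cells the log2 ratios of opposite sign for day 13 against day 8 were Cebpa 0.37, Col4a1 0.83, Cxcl15 0.64, Cxcl5 0.30, Foxa2 0.58, Hp 0.71, Ly6k 0.0530, Scd1 0.28 and Sftpb 0.63. Over all filtered cells the log2 ratios of opposite sign for day 20 against day 13 were Ager -0.11, Cebpa -0.0856, Lamp3 -0.0252, Mcm3 0.29, Mcm5 0.20, Mcm6 0.38, Pclaf 0.46, Rrm2 0.23 and Uhrf1 0.30. Over all filtered cells the log2 ratios of opposite sign for day 20 against day 0 were Ankrd1 1.59, Cd74 -1.43, Fn1 -1.19, Fstl1 -0.32, H2-DMa -0.96, H2-DMb1 -0.77, Msln -0.91, Spred2 -0.16 and Upk1b -1.29. With doublets kept the log2 ratio for day 8 against day 0 turned sign for Fcer1g -0.27. With doublets kept the log2 ratio for day 20 against day 0 turned sign for Fcer1g -0.88.

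Shares of the epithelial, AT1, AT2, airway secretory, myeloid and mesenchymal classes are listed where they lay outside the interval of the main value, while those of other classes are only counted above. The main share of epithelial cells was 15.7, 8.46, 20.4 and 11.6% at days 0, 8, 13 and 20. With Leiden resolution 0.5 the class shares were myeloid 8.83% at day 0, 83.7% at day 8, mesenchymal 6.96% at day 8. With Leiden resolution 2.0 the class shares were AT2 1.57% at day 0, 6.82% at day 8, 7.39% at day 13, 8.54% at day 20, airway secretory 0.0146% at day 0, 0.572% at day 8, 3.04% at day 13, 1.70% at day 20, myeloid 12.5% at day 0. With clustering of each library on its own the class shares were epithelial 17.3% at day 0, 10.5% at day 8, airway secretory 2.20% at day 0, 4.35% at day 13, myeloid 31.4% at day 0, 81.7% at day 8, AT2 7.44% at day 8, mesenchymal 6.52% at day 8, 32.0% at day 20, AT1 0% at day 13. With no cell filter the class shares were AT2 1.59% at day 0, myeloid 28.2% at day 0, 58.6% at day 8, 52.6% at day 13, 49.0% at day 20, epithelial 34.1% at day 13, 12.9% at day 20, airway secretory 23.7% at day 13, 4.34% at day 20, mesenchymal 12.7% at day 13. With the stricter cell filter the class shares were epithelial 18.3% at day 0, 7.24% at day 8, 10.9% at day 20, AT1 7.84% at day 0, AT2 1.57% at day 0, 4.43% at day 8, 6.22% at day 13, myeloid 11.4% at day 0, 85.6% at day 8, 55.0% at day 20, mesenchymal 6.56% at day 8. With doublets kept the class shares were epithelial 20.4% at day 0, 10.2% at day 8, 22.6% at day 13, 13.9% at day 20, AT1 7.52% at day 0, AT2 4.78% at day 0, myeloid 12.2% at day 0, 59.1% at day 13, 36.8% at day 20, airway secretory 3.60% at day 8, 12.5% at day 13, 5.57% at day 20, mesenchymal 7.20% at day 8. With Scrublet automatic threshold the class shares were epithelial 23.0% at day 0, 22.6% at day 13, 14.0% at day 20, myeloid 9.33% at day 0, 83.7% at day 8, 62.2% at day 13, 50.3% at day 20, airway secretory 2.72% at day 8, 12.2% at day 13, 5.59% at day 20, mesenchymal 6.41% at day 8.

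When cells were thinned to 1000 UMIs the shares of epithelial cells with a UMI that moved for Ager, Sftpc and EGFP at days 0 and 20 were Sftpc 20.5% at day 0, EGFP 52.7% at day 0, Ager 52.8% at day 20, Sftpc 71.7% at day 20, EGFP 9.98% at day 20. When cells were not thinned the shares of epithelial cells with a UMI that moved for Ager, Sftpc and EGFP at days 0 and 20 were Ager 56.9% at day 0, Sftpc 36.9% at day 0, EGFP 71.9% at day 0, Ager 84.3% at day 20, Sftpc 97.8% at day 20, EGFP 40.2% at day 20. Requiring more reporter UMIs per cell moved most EGFP-dominant shares upward. Such a minimum also selects by reporter level, so these are not read as better estimates of the labelled share. With at least 4 and 8 reporter UMIs the AT2-like share of day 20 was 35.6% and 71.2%, and the airway secretory-like share of day 13 51.6% and 71.8%. With doublets kept and cells clustered again the AT2-like share of day 0 was 44.0%, against 81.8% with doublets removed.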

Other observations

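Sub-clusters of the epithelial cells were formed and compared after the data were seen, as were both tests of the myeloid cells below; the tests of the reporters and of Y-linked genes were written first, apart from the additions named there. A sub-cluster of 179 cells (46, 79 and 54 at days 8, 13 and 20), named AT1 by the naming rule, held AT1 and AT2 genes in its summed counts. Such sums do not show whether single cells carried both. Its Ager level was 6730.1 CPM and its Hopx level 2286 CPM, against 25395 and 17763 CPM in the AT1-like sub-cluster of day 0, while Rtkn2 was 7.15 against 1256 CPM. Sftpc stood at 103980.0 CPM, Gramd2 at 88.7 CPM and EGFP at 695 CPM. Sub-clusters named AT2 included 111 cultured cells with cycling genes (81 of day 8, Mki67 343 CPM), 127 cultured cells with interferon-inducible genes (115 of day 20, Iigp1 1176 CPM) and 208 cells, 76 of them from day 0, with Lamp3 at 1249 CPM and EGFP at 1307 CPM. A sub-cluster of 126 airway cells, all from day 13, carried EGFP at 2112 CPM with tdTomato at 9.32 CPM and mesothelin, Msln, at 3727 CPM, whereas the Krt13-high sub-cluster of the same day had EGFP at 7.06 and tdTomato at 201 CPM.

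Myeloid-like cells were the largest class of each bead-enriched culture library. The feeder fibroblasts as their source are argued against by the reporter: tdTomato in myeloid-like cells was 104, 56.7 and 53.3 CPM at days 8, 13 and 20, at least 11.5 times (interval from 9.23) the level in mesenchymal-like cells of the same library, and up to 27.1 times. Sorted lung cells as their source had what it needs, since day 0 held 1051 myeloid-like cells with tdTomato at 197 CPM, so these cells may descend from lung myeloid cells that passed the sort. Some of them carried cycling transcripts: clusters 27 and 28 held 215 and 949 of the day 8 cells. The mean log2 deviation of cycling markers from all clusters was 3.51 and 3.35 there. How far multiplication, better survival or sticking to the beads made up the myeloid-like share stays open and was not tested.

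AT2-like cells of the cultures held both EGFP-dominant and tdTomato-dominant cells. If free RNA and low reporter counts made the second kind, they should vanish among cells with many reporter UMIs. Yet among day 20 cells with at least 8 reporter UMIs 18 of 80, or 22.5% (13.9 to 33.2), were tdTomato-dominant. The bound set in advance, at least 20%, was thus met by the point value alone. Measures chosen after that outcome argue further against free RNA: tdTomato in AT2-like cells was at least 33.7 times (interval from 24.2) and EGFP at least 129 times (from 92.5) the mesenchymal-like level in each culture, and 5 of those cells (6.25%) lay between the ranges. Doublets with macrophages, which carry tdTomato, are argued against for most of these cells by C1qa, C1qb and Tyrobp. Their summed median was 23.3 CPM in tdTomato-dominant and 57.2 CPM in EGFP-dominant cells, a ratio of 0.407 (interval 0 to 0.749). Such medians rest on few UMIs per cell and cannot show whether a minority were doublets. Cells of more than a single origin may therefore be mixed in this class, but whether tdTomato-dominant cells come from unlabelled AT2 cells in the sorted sample, where 8 of 66 AT2-like cells were tdTomato-dominant (EGFP-dominant 81.8%, and 44.0% with doublets kept), or from other unrecombined cells stays open.

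In airway secretory-like cells of day 13 a UMI of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d or Uty was seen in 18 of 313 EGFP-dominant cells (5.77 CPM, 3.89 to 8.23) and in 240 of 347 tdTomato-dominant cells (105 CPM, 98 to 112). Shallow cells are argued against, as the EGFP-dominant cells had 80.5% of the median depth of the others. For a source without a Y chromosome the bound set in advance was 4-fold for each of the 4 genes. The point values alone met it: the smallest was 9.93-fold lower, and the intervals reached down to 3.67. These are the genes and cells in which the pattern was seen. That outcome therefore restates the pattern gene by gene and is no separate evidence for such a source. The test of Y chromosome loss could not decide. The X-linked partners Kdm6a, Ddx3x, Eif2s3x and Kdm5c were 1.36 times as high in EGFP-dominant as in tdTomato-dominant cells (1.26 to 1.47). That interval lay above the range set in advance for loss and reached below the bound set in advance against it. Many of these cells also lay in different sub-clusters. At day 13 a sub-cluster held 125 EGFP-dominant and 0 tdTomato-dominant cells, and another 6 and 109. The X-linked and Y-linked ratios carry that difference too. Among ciliated-like cells of day 13 a Y-linked UMI was likewise seen in 6 of 53 EGFP-dominant (7.84 CPM) and 16 of 27 tdTomato-dominant cells (68.0 CPM). The split was not as sharp in other cells of day 13. Such a UMI was seen in 1 of 73 tdTomato-dominant Krt13-high cells (0.638 CPM), a class with no EGFP-dominant cells to compare. It was seen in 32 of 107 EGFP-dominant AT2-like cells (45.8 CPM). All AT2-like cells of that day had it in 203 of 575 (55.4 CPM, 50.6 to 60.5), so a smaller difference by reporter is not excluded there. The EGFP-dominant airway cells may come from a different animal than the tdTomato-dominant ones, but this stays open, and the sex and number of mice are not given in the sources used here.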
